A study of Drosophila melanogaster with 60 samples.

How the data were processed

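CUT&RUN, in which an antibody tethers a nuclease to chromatin and the released DNA is sequenced, was done on brains of adult male Drosophila melanogaster with 1 of 2 antibodies per library. One antibody bound H3K4me3, a histone mark found mostly at the starts of transcribed genes, and the other bound RNA polymerase II (RNAPolII). Per the labels' protocols, brains were dissociated with collagenase, 15 brains went into each H3K4me3 library and 30 into each RNAPolII library, libraries were made with the CUTANA kit, and sequencing on a NextSeq gave paired reads of 75 bp. The 60 libraries covered 5 genotypes, 2 housings and 3 biological replicates with each antibody. All 60 were used in the comparisons. Samples were grouped by the genotype and housing in their labels, and columns of the deposited tables were joined to samples by the library name in each sample's description, because the CS replicates carry other numbers in the tables than in the sample titles.

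Trim Galore, Bowtie2, MACS2, DESeq2 and ChIPseeker are named in the submitters' processing notes, without versions or order. The genome build, the read counter, the merging of peaks and any filter on reads or peaks are not given in the sources used here. The deposited tables, 1 per antibody, hold signal on a common set of peaks for all 30 libraries: reads per peak that the authors divided by 1 size factor per library. In each column every value was a whole multiple of the value of 1 read, to within 0.01 reads in 100% of peaks, so whole reads were recovered by dividing by that step. For 4 H3K4me3 libraries (CS GH 2, fru GH 1, fru SH 1 and Or47b SH 2) and 2 RNAPolII libraries (CS SH 2 and Or67d SH 3) the step lay close to 1 or low counts were missing. The step was less sure there, and those libraries were left out of the tests on whole reads only. No 2 libraries held the same reads.

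Peak positions are those of the deposited tables, whose build is not given in the sources used here. Gene symbols came from the overlap of a peak with gene spans of the Release 6 plus ISO1 MT RefSeq table, used for names only. Because that table was used without strand or exons, the place of a peak within a gene is not given, and a peak can lie over more than 1 gene. The names fit the H3K4me3 peaks: 83% of H3K4me3 peaks with a mean value of at least 100 lay over the end of a gene, against 40.5% after all peaks were shifted by 5000 bp and 30.4% after a shift by 50000 bp. RNAPolII peaks were broad, and 54.5% of them did so against 52.9% and 50.7% after the shifts, so an RNAPolII value stands for a stretch of several genes or gene parts and not for a promoter.

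Peaks with a mean value of at least 10 over the 30 libraries of an antibody were tested, 14513 of 14894 with H3K4me3 and 21076 of 21113 with RNAPolII. Values were taken as log2 of the deposited value plus 1 and fitted with limma 3.58.1 in R 4.3.3 (lmFit on 10 group means, eBayes with a mean trend). Changes below are log2, with an adjusted p by the Benjamini-Hochberg method within each comparison and a threshold of 0.05, two-sided. For each antibody 13 comparisons were made: social housing alone against in a group (SH minus GH) in each of 5 genotypes, each of 4 mutants minus CS averaged over both housings, and the difference of the housing effect of each mutant minus that of CS. Means are of deposited values, with the SD between libraries. A value of 0 in all libraries of a side gives no fold, only a bound against a floor of 3 reads per library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

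In data simulated on the CS housing comparison, limma called 41.8% of 67 peaks changed by 2-fold and 80.3% of 66 changed by 4-fold with H3K4me3, and 71.6% and 93.9% with RNAPolII. Of H3K4me3 peaks with a mean value over 50 it called 88% at 2-fold. In data simulated on the dsx comparison with CS it called 68.7% at 2-fold with H3K4me3 and 92.5% with RNAPolII. It called 7 unchanged peaks of the 14513 in the H3K4me3 housing simulation, 9 in that of dsx, 5 of the 21076 in the RNAPolII housing simulation and 14 in that of dsx. Peaks were simulated independently, without the differences in the balance of strong and weak peaks that real libraries showed. These rates may therefore not hold for the real data.

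Sets of genes were written down before the data were examined, as were the comparisons, most of the other settings tried and the rule for naming genes. There were 25 lists with 856 genes, of which 844 matched a symbol, and ribosomal protein genes were found by symbol. Each list was tested with camera of limma, with 1 peak per gene (that of highest mean) and a preset correlation of 0.01, adjusted over the 25 lists within a comparison, and again with a correlation estimated from the data. Named peaks are, per comparison and direction, up to 10 with the largest log2 change among those past the threshold whose libraries did not overlap between the sides compared (no such rule for differences of housing effects), at most 1 per gene. Where fewer than 10 passed, the 10 with the smallest unadjusted p were looked at, and up to 4 members per list and the targeted genes were named in any case. Of these the text gives the peaks that bear on each account. RNAPolII peaks that overlap a lost H3K4me3 peak were added after their values were seen. Without a change, 6 libraries against 6 fail to overlap in 0.216% of peaks and 3 against 3 in 10%.

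A stretch was defined as at least 3 neighbouring RNAPolII peaks in a row past the threshold in the same direction, joined across a gap of 1 peak and kept with at least 5 calls. Its level in a library is the sum over its peaks as a percent of the CS mean. Sharing between mutants was set against the product of the called shares (independence), against 20 simulations of unchanged groups that share their CS libraries, and against calls in which the 2 mutants were compared with different CS libraries. Correlations across peaks or genes carry a jackknife SE over libraries. The spread of a library between strong and weak peaks is the median log2 value of the 25% of peaks with the highest mean minus that of the lower 50%, compared between groups with exact permutation tests, two-sided. Shares of called peaks per chromosome were compared with Fisher's exact test, which treats neighbouring peaks as independent although they can move together.

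Replicate numbers were checked for pairing: the residuals of GH and SH libraries of a genotype with the same number correlated at over 0.1 in 7 of 15 H3K4me3 and 4 of 15 RNAPolII cases. Only in H3K4me3 of fru did all 3 (0.135, 0.125 and 0.317), so replicates were treated as unpaired and the replicate block is an alternative. By title number, however, replicate 3 had the highest H3K4me3 spread between strong and weak peaks in every group but CS SH. There replicate 1 was at 5.32 and replicate 3 at 5.26. The RNAPolII libraries that stood apart, Or47b GH 3, Or47b SH 3 and Or67d GH 3, carry that number too. A number may thus mark a shared preparation, which the unpaired tests do not take into account. With the block, fru had 0 H3K4me3 housing calls, as without it, but 4 H3K4me3 counts (housing in Or47b, and Or47b, fru and dsx against CS) rose by over 1.5 times and are given with the results. The block matched CS to mutant libraries by the number in the sample titles, while the CS columns carry other numbers, and which numbering marks a shared preparation is not known. The blocked counts against CS therefore rest on an uncertain match. Alternatives tried were a pseudocount of 10, no filter, TMM rescaling, quantile normalization, a fit on only the libraries compared, the replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, leaving out each library, and for lists the estimated correlation and the mean of all peaks of a gene. Added after the results were seen were a covariate for the spread between strong and weak peaks, leaving out 3 RNAPolII libraries together, lists on peaks over 1 gene only, and a list without the mutated gene. Positions were handled with GenomicRanges 1.54.1. Raw reads were not used here.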

Results

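H3K4me3 and RNA polymerase II were mapped by CUT&RUN in brains of male flies of 5 genotypes kept in groups (GH) or alone (SH). Canton-S (CS) was the wild type. A mutant could also differ from CS in strain background, and genotype and background cannot be told apart in the comparisons with CS below. Or47b and Or67d flies lacked odorant receptors that detect pheromones, fru flies carried the alleles fruLexA and fru4-40 of the male courtship regulator fruitless, and dsx flies carried the alleles dsxf00683-d07058 and dsxf01649-d09625 of the sex regulator doublesex. Each genotype and housing had 3 libraries per antibody, 60 in all, so a mutant was compared with CS on 6 libraries against 6 and housing within a genotype on 3 against 3. H3K4me3 libraries held from 2309386 to 9269525 reads in peaks, with a median of 4004688. RNAPolII libraries held from 3007711 to 6459322, with a median of 3602329. H3K4me3 peaks had a median length of 961 bp, and 1706 of the 14894 lay over no gene. RNAPolII peaks had a median length of 2256 bp, and 4105 of the 21113 lay over no gene. The median SE of a log2 change was 0.307 for housing and 0.217 for genotype with H3K4me3, and 0.192 and 0.136 with RNAPolII. Peaks named below for the size of their change between a mutant and CS had 6 of 6 mutant libraries on one side of all 6 CS libraries, while libraries could overlap at the mutated genes, at members of gene lists and at RNAPolII peaks set beside a lost H3K4me3 peak.

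The mutated genes showed what each allele did to the signal at its own locus. In dsx flies RNAPolII was nearly absent from 12 neighbouring peaks over doublesex on 3R between 7927368 and 7964916. It was 0.378 ± 0.586 (SD, n = 6) against 213 ± 22.2 in CS at the first, 7927368 to 7934294 (log2 change -7.37, adjusted p = 4.61e-27). At the last peak it was 0.524 ± 0.575 against 204 ± 21, from 7962582 to 7964916 (-7.16, adjusted p = 1.36e-23). H3K4me3 was lost there too: the peak from 7962564 to 7963974 fell from 94.1 ± 12.1 to 0.296 ± 0.46 (-6.26, adjusted p = 2.18e-44). That from 7959738 to 7960791 fell from 38.8 ± 9.96 to 0.0762 ± 0.187 (-5.19). At 7947071 to 7947730 H3K4me3 was 0 in all 6 dsx libraries against 33.5 ± 9.94 in CS. Missing DNA in this part would take away the signal of both antibodies too, and reads of total DNA were not used here. The size of such a change, against values near 0, depended on the setting: it ranged over the settings from -8.23 to -3.33 at the H3K4me3 peak from 7962564, and always fell. Beyond the lost part, the dsx peak from 7966046 to 7971612 kept its RNAPolII, with 222 ± 17.3 against 245 ± 17.8 (-0.14, adjusted p = 0.34), and the H3K4me3 peak from 7966177 to 7968228 did not pass (-0.30, adjusted p = 0.297).

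In fru flies the RNAPolII signal at fruitless fell to about the midpoint between CS and 0 at peaks over one part of the gene, and peaks over the other part did not pass the test. RNAPolII on 3R fell from 1122 ± 214 to 538 ± 79.5 at 18545132 to 18547416 (-1.05, adjusted p = 0.00715). It also fell from 230 ± 7.58 to 118 ± 19.6 at 18507619 to 18514006 (-0.97, adjusted p = 6.42e-09) and from 118 ± 8.29 to 60 ± 10.2 at 18484274 to 18487891 (-0.97, adjusted p = 1.28e-07). The 11 fru peaks between 18415868 and 18483179 had log2 changes from -0.25 to 0.18, none past the test. H3K4me3 fell at 18544985 to 18547433 from 303 ± 39.1 to 190 ± 36.4 (-0.69, adjusted p = 2.9e-06) and at 18517537 to 18517981 (-1.11, adjusted p = 0.0414), while the other 8 fru peaks did not pass. Neither antibody had a peak over Or67d, and H3K4me3 had none over Or47b, so those mutations could not be seen at their loci. The RNAPolII peak over nompA, Or47b and sha on 2R from 11318614 to 11327118 fell in Or47b flies from 283 ± 28.3 to 216 ± 27.9 (-0.39, adjusted p = 0.0218). At white, which sets eye pigment and which the labels give as mutant only in dsx flies, H3K4me3 on X from 2788905 to 2791271 rose in dsx (213 ± 22.0 against 134 ± 18.0, 0.67, adjusted p = 1.59e-05) and that from 2791879 to 2793105 fell in Or67d (11.1 ± 4.93 against 44.7 ± 9.13, -1.99, adjusted p = 2.52e-10). RNAPolII from 2788922 to 2793646 rose in Or47b (369 ± 35.8 against 277 ± 19.6, 0.41, adjusted p = 0.0051) and dsx (0.39, adjusted p = 0.00506) and fell in Or67d (182 ± 19.1, -0.60, adjusted p = 7.97e-06). RNAPolII from 2795786 to 2797709, over white and kirre, fell in dsx (36.6 ± 7.55 against 67.2 ± 9.93, -0.87, adjusted p = 0.000131) and Or67d (-0.58, adjusted p = 0.0224), so peaks over white moved both ways in dsx.

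Whether loss of the Or47b receptor alters brain chromatin was asked by comparing Or47b with CS. Changes were few, and the clearest were gains and losses at single genes, with H3K4me3 mostly on chromosome 2. With H3K4me3 62 peaks rose and 55 fell, and 47 of these 117 moved by over 2-fold. edgeR called 111 and DESeq2 87, and without CS GH 3 there were 200. After quantile normalization 119 rose and 86 fell. A replicate block gave 262; this and the blocked counts below match CS to mutant libraries by the number in the sample titles, and whether that number marks a shared preparation is not known. The kinase gene hppy rose on 2R at 19218828 to 19220031 from 21.9 ± 5.76 to 151 ± 11.1 (2.78, adjusted p = 1.93e-16). d4 rose at 5259003 to 5260870 from 19.3 ± 9.28 to 78.3 ± 6.85 (2.12, adjusted p = 5.06e-12) and the glycolytic gene Pfk at 10109931 to 10111891 from 521 ± 58.4 to 939 ± 146 (0.84, adjusted p = 1.67e-11). E2f2 rose on 2L at 21154013 to 21154823 (254 ± 44.9 against 133 ± 23.2, 0.93). The lipid enzyme gene Agpat2 fell on 2L at 8462127 to 8462695 from 129 ± 18.2 to 24.1 ± 8.96 (-2.44, adjusted p = 9.17e-17). CG31637 at 6516159 to 6516663 was 0 in all 6 Or47b libraries against 15.6 ± 3.61, at least 4.98-fold lower. Msp300 (-1.67), apterous (-1.02) and the ryanodine receptor gene RyR fell too. RyR at 2R 8862476 to 8862873 (-1.10, adjusted p = 0.00181) was not called by edgeR or DESeq2.

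With RNAPolII 64 peaks rose and 54 fell in Or47b, of which 39% lay on unplaced sequences. There were 612 calls with the covariate for the spread between strong and weak peaks (497 higher, 115 lower) and 181 without the 3 libraries that stood apart (Or47b GH 3, Or47b SH 3 and Or67d GH 3). hppy rose here too, on 2R at 19217962 to 19226659 (715 ± 20.7 against 494 ± 30.7, 0.53, adjusted p = 1.56e-06). Ir41a, an ionotropic receptor gene, rose at 4960053 to 4962795 from 18.6 ± 5.88 to 82.7 ± 16.5 (2.12, adjusted p = 5.01e-10). CR11023 at the tip of 2L, 7557 to 9324, was nearly lost (0.699 ± 1.41 against 80.6 ± 14.7, -5.84, adjusted p = 8.11e-17). RyR at 8862349 to 8863061 fell with RNAPolII as well (-0.94, adjusted p = 0.000473), as did Msp300 on 2L at 5197260 to 5206472 (477 ± 74.5 against 692 ± 21.9, -0.55, adjusted p = 0.000125). The neuroblast factor gene pdm2 (-0.65) and Gpdh1 (-0.56, adjusted p = 0.00693) fell. The Gpdh1 call was lost in a fit on only the libraries compared. Of all tested peaks on chromosome 2, which carries Or47b, 0.656% were called against 0.0894% on X and 3 (ratio 7.34, Fisher's exact test, adjusted p = 1.06e-11). With H3K4me3 the shares were 1.25% and 0.281% (ratio 4.46, adjusted p = 1.61e-11).

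Gene lists moved little in Or47b. With H3K4me3 and against a median of 0.043 over all genes, detoxification genes were lower (median -0.175, adjusted p = 0.0119). So were eye and photoreceptor genes (-0.134, adjusted p = 0.0375) and immune genes (-0.133, adjusted p = 0.0375). Ribosomal protein genes were higher (0.076, adjusted p = 0.0119). The 4 medians after quantile normalization were -0.089, -0.104, -0.074 and -0.005. No member of these 4 lists rose or fell over all genes tested, with 0 of 23, 27, 14 and 70 calls by limma, and adjusted over the list alone 1 detoxification gene did. With an estimated correlation the adjusted p were 0.185, 0.125, 0.125 and 0.964, and with the covariate for the spread between strong and weak peaks none of the 4 lists stayed past the test. Single members of other lists fell: the insulator gene CTCF (-0.32, adjusted p = 0.0286) and FASN2 (-0.86, adjusted p = 0.00198).

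Loss of Or67d, which detects a male pheromone, came with many H3K4me3 calls. Strong peaks were higher and weak peaks lower: the median log2 change was 0.24 in the 25% of peaks with the highest mean and -0.35 in the weaker 50%. Beyond that spread, whole peaks were lost at Rab26, mthl8 and alpha-Man-IIb. Counts were 2540 higher and 1810 lower, of which 428 moved by over 2-fold. The share that was higher depended on the scaling: after TMM rescaling 1686 rose and 2209 fell. edgeR gave 755 and 821 and DESeq2 1454 and 563, but these tests also left out CS GH 2. There were 1096 calls after quantile normalization, 1869 without CS GH 2, 2458 without CS SH 2 and 2678 without Or67d SH 3. With the spread between strong and weak peaks of each library as a covariate, 115 of the 4350 remained. The spread between strong and weak peaks of a library was 5.84 ± 0.173 in Or67d against 5.24 ± 0.282 in CS (exact permutation p = 0.00433, n = 6 each). In dsx it was 5.62 ± 0.229 (exact permutation p = 0.0281). It was 5.46 ± 0.375 in Or47b and 5.46 ± 0.322 in fru (exact permutation p = 0.292 and 0.238).

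**Figure D1:**
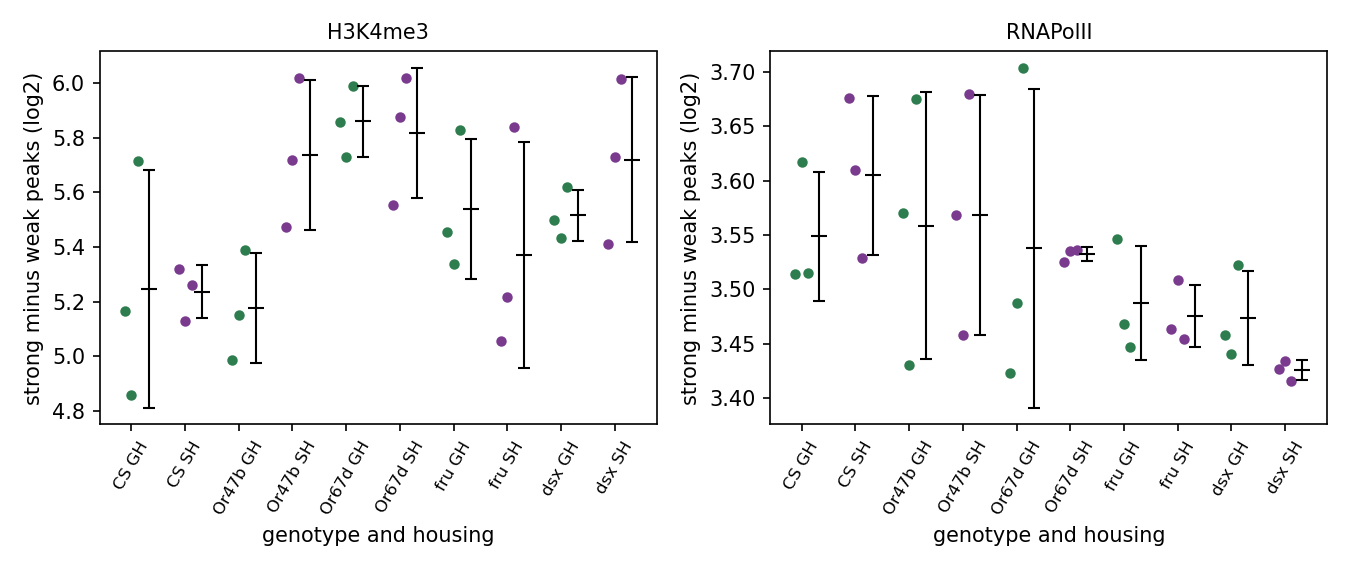
Spread between strong and weak peaks in each library (median log2 value of the strongest 25% minus that of the weaker 50% of peaks, y axis) by genotype and housing, with GH in green, SH in purple and the mean ± SD of 3 libraries as black bars. With H3K4me3, Or67d lay above CS (5.84 against 5.24), and Or47b SH lay above Or47b GH (5.74 against 5.18).

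In Or67d flies H3K4me3 at Rab26, a vesicle GTPase gene, fell on 3L at 21321564 to 21322726 from 169 ± 23.3 to 0.2 ± 0.49 (-7.21, adjusted p = 5.71e-54). At mthl8 it fell at 21688 to 23315 from 202 ± 78.2 to 0.797 ± 0.922 (-6.90, adjusted p = 1.8e-51). Over the settings these log2 changes ranged from -9.46 to -4.12 at Rab26 and from -8.19 to -4.22 at mthl8. alpha-Man-IIb on 3R at 15817525 fell from 17.0 ± 6.97 to 0.227 ± 0.557 (-3.88). CG1113 fell from 169 ± 18.7 to 8.51 ± 5.27 (-4.43) and nebu on 3L at 12839970 to 12840950 from 146 ± 37.6 to 16.2 ± 7.43 (-3.13). Gains were at CG9297 (73.9 ± 14.0 against 5.39 ± 2.8, 3.69) and CG3397 on 3R at 11983705 to 11984288 (16.1 ± 4.64 against 0.451 ± 0.731, 3.64, from 1.30 to 4.44 over the settings, adjusted p = 6.33e-10). H3K4me3 rose at spartin on 3R at 4654715 to 4655397 (294 ± 46.8 against 90.7 ± 20.1, 1.70, adjusted p = 1.71e-16). It rose at the mitochondrial carrier gene Bmcp on 3L at 11720847 to 11722538 (1004 ± 64.4 against 451 ± 37.2, 1.15, adjusted p = 1.08e-17) and the Hedgehog receptor gene ptc (1.10, adjusted p = 2.32e-08). The calls at spir (-1.84), Pzl (-1.70) and Src64B (1.53) were lost with the covariate.

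With RNAPolII 107 peaks rose and 120 fell in Or67d, with 176 calls by edgeR and 206 by DESeq2. These are fewer than with H3K4me3, but with the covariate the order turned, to 746 RNAPolII calls (558 higher, 188 lower) against 172 with H3K4me3. Without Or47b GH 3, Or47b SH 3 and Or67d GH 3, which stood apart from the other libraries, there were 442 RNAPolII calls. At mthl8 RNAPolII was lost along with the mark: the peak on 3L from 21598 to 23274, which overlaps the lost H3K4me3 peak, fell from 42.3 ± 11 to 0.506 ± 0.86 (-4.97, adjusted p = 3.18e-15). The next peak, from 23608 to 27313, fell from 130 ± 32.4 to 0.472 ± 0.786 (-6.58, adjusted p = 1.3e-21). Whether DNA is missing at mthl8 was not tested. Within Rab26 the peak from 21324631 to 21325030 fell from 40.2 ± 11.4 to 0.168 ± 0.412 (-5.14, adjusted p = 3.58e-16), while the peak over the H3K4me3 loss at 21321564, which also covers Pc, fell only from 1033 ± 117 to 657 ± 123 (-0.66, adjusted p = 0.00272). The RNAPolII peak over the loss at alpha-Man-IIb fell from 361 ± 31.9 to 289 ± 20.5 (-0.32, adjusted p = 0.0166). Bmcp rose at 11719668 to 11723078 from 142 ± 13.8 to 285 ± 24.8 (1.00, adjusted p = 2.12e-10) and the synaptic fusion gene Snap25 at 24176147 to 24181818 from 199 ± 12.9 to 399 ± 40.3 (0.99, adjusted p = 1.64e-09). The histamine transporter gene lovit (1.30) rose, but its call was lost when any 1 of 7 libraries was left out. CTCF fell from 1380 ± 82.1 to 873 ± 46.6 (-0.66, adjusted p = 2.86e-08). Of 8 H3K4me3 peaks that fell below 5% of CS, 3 lay in RNAPolII peaks that did so too. On chromosome 3, which carries Or67d, 1.35% of RNAPolII peaks were called against 0.287% on X and 2 (ratio 4.69, Fisher's exact test, adjusted p = 1.34e-17), while with H3K4me3 the shares were 29.5% and 29.8% (ratio 0.991, adjusted p = 0.763). Chromosome 4, outside that comparison, had H3K4me3 calls at 52.8% of its peaks.

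**Figure D2:**
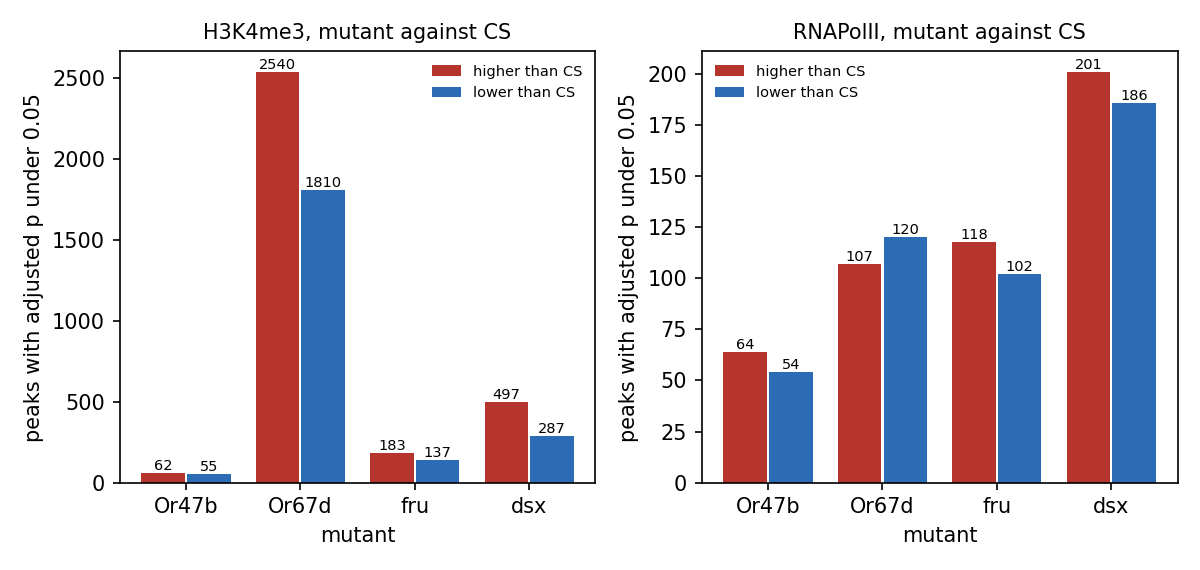
Number of peaks (y axis) higher (red bars) and lower (blue bars) than in CS at an adjusted p under 0.05 in each of the 4 mutants (x axis), with H3K4me3 on the left and RNAPolII on the right, on scales of their own. With H3K4me3 Or67d had 2540 higher and 1810 lower peaks, and with RNAPolII the counts per mutant were between 118 and 387.

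In Or67d 10 lists passed with H3K4me3, against a median of 0.16 over all genes. Ribosomal protein genes were higher (median 0.302, adjusted p = 4.7e-09), with 59 of 70 up and 64 called adjusted over the list alone, such as RpL27 (561 ± 49.0 against 386 ± 61.6, 0.55, adjusted p = 2.68e-05). Synaptic genes were higher (0.292, adjusted p = 0.0188; 19 rose and 2 fell, 26 called adjusted over the list alone), such as the vesicle priming gene unc-13 (1818 ± 124 against 1312 ± 265, 0.49, adjusted p = 0.000189), while Syn fell (-0.86, adjusted p = 0.00171). Chromatin genes were higher (0.243, adjusted p = 0.0153; 25 rose and 2 fell, 29 over the list alone), such as Su(z)12 (0.40, adjusted p = 0.000638), while CTCF fell (-0.36, adjusted p = 0.00119). Learning genes were higher (0.249, adjusted p = 0.0401; 10 rose, 14 over the list alone), with CaMKII at 706 ± 84.5 against 490 ± 112 (0.55, adjusted p = 0.000149). Lower were detoxification genes (-0.346, adjusted p = 0.00118; 4 fell, 4 over the list alone) and olfactory genes (-0.457, adjusted p = 0.0037; 1 rose and 1 fell, 0 over the list alone). So were muscle genes (-0.311, adjusted p = 0.0302; 3 rose and 6 fell, 14 over the list alone) and eye and photoreceptor genes (-0.205, adjusted p = 0.0353; 5 rose and 5 fell, 10 over the list alone). Neuropeptide genes (-0.25, adjusted p = 0.0353; 1 rose and 2 fell, 1 over the list alone) and immune genes (-0.443, adjusted p = 0.0476; 2 rose and 5 fell, 7 over the list alone) were lower as well. Toll (-0.72, adjusted p = 0.000938) and rdgC, an eye phosphatase gene (-0.56, adjusted p = 2.08e-05), fell. With an estimated correlation the adjusted p was 0.614 for ribosomal, 0.741 for synaptic, chromatin and learning, 0.161 for muscle, 0.239 for olfactory and 0.154 for the other 4 lists. With the covariate 0 of the 10 lists stayed past the test. With the mean of all peaks of a gene, synaptic and learning genes turned lower without passing (adjusted p = 0.696 and 0.456), and 7 of the 10 lists stayed. On peaks over 1 gene only 3 stayed. After quantile normalization the medians were 0.051 for ribosomal protein, 0.063 for synaptic, 0.009 for chromatin and 0.039 for learning genes. They were then -0.123 for detoxification, -0.207 for olfactory, -0.059 for muscle and for eye, -0.099 for neuropeptide and -0.202 for immune genes. Outside these lists roX2 rose (0.57, adjusted p = 0.000493). With RNAPolII chromatin genes were lower (-0.083, adjusted p = 8.93e-05; 2 fell, 3 over the list alone; adjusted p = 0.509 with an estimated correlation).

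The fru comparison asked what the courtship regulator does in the male brain, but it could not separate the fru alleles from the strain background. RNAPolII was lower over a stretch of neighbouring genes from fru to fray. Elsewhere bol, NaPi-T and spartin rose, and sand and per fell, as they did in dsx. H3K4me3 rose at 183 peaks and fell at 137, with 289 by edgeR and 256 by DESeq2. There were 762 after quantile normalization, 641 without CS GH 3, 206 without CS SH 2, 695 without fru SH 1 and 211 without fru SH 3. A replicate block gave 702. RNAPolII rose at 118 and fell at 102, with 430 calls in a fit on only the libraries compared and 921 with the covariate (745 higher, 176 lower). The germline translation gene bol rose with both antibodies, on 3L at 9105402 to 9106258 with H3K4me3 (37.1 ± 7.84 against 10.04 ± 2.37, 1.79, adjusted p = 2.07e-05). With RNAPolII it rose at 9099617 to 9106497 (377 ± 38.0 against 168 ± 7.68, 1.15, adjusted p = 1.95e-11). H3K4me3 also rose at NaPi-T on 2R at 14842813 to 14843829 (118 ± 15.1 against 12.1 ± 4.31, 3.25, adjusted p = 2.04e-17). It rose over MTF-1 and CG42526 (346 ± 39.0 against 104 ± 18.3, 1.73, adjusted p = 5.31e-21) and at spartin (268 ± 24 against 90.7 ± 20.1, 1.58, adjusted p = 3.86e-15). It fell at the potassium channel gene sand on 2R at 8093021 to 8094591 from 588 ± 72.0 to 25.6 ± 2.77 (-4.47, adjusted p = 5.25e-45). It fell at rosy (ry) on 3R at 13035904 to 13037589 from 51.0 ± 15.7 to 4.69 ± 4.21 (-3.56, adjusted p = 3.11e-16) and at the clock gene per on X at 2684594 to 2687770 from 462 ± 63.7 to 284 ± 39.0 (-0.70, adjusted p = 1.67e-07). RNAPolII at the peak over sand, uno and Tmem63, which overlaps that H3K4me3 peak, was 468 ± 54.3 against 524 ± 28.2 (-0.17, adjusted p = 0.386).

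With RNAPolII in fru Nlg3, a neuroligin gene, fell from 268 ± 19.4 to 165 ± 33.6 (-0.71, adjusted p = 0.000642) and also lost H3K4me3 (638 ± 115 against 890 ± 77.9, -0.50, adjusted p = 0.000148). Nlg1 fell from 309 ± 14.9 to 214 ± 31.6 (-0.54, adjusted p = 1.29e-05) and Cip4 from 214 ± 19.6 to 104 ± 6.04 (-1.04, adjusted p = 6.25e-11). The translation regulator gene Fmr1 fell from 444 ± 29.3 to 342 ± 23.4 (-0.38, adjusted p = 0.00472). The heterochromatic gene Myo81F rose from 18.7 ± 6.43 to 182 ± 20.0 (3.27, adjusted p = 1.24e-13) and hbt from 0 in all 6 CS libraries to 23.5 ± 7.3, at least 8.06-fold higher. CG1304 (-1.50) was lost as a call without fru GH 2 or fru SH 3. With RNAPolII synaptic genes were lower as a list (median -0.09, adjusted p = 0.00991; 2 fell, 2 adjusted over the list alone), as were chromatin genes (-0.098, adjusted p = 0.0166; limma called 0), with adjusted p = 0.602 for both with an estimated correlation. With H3K4me3 detoxification genes were lower (-0.221, adjusted p = 0.0085; limma called 0) and ribosomal protein genes higher (0.089, adjusted p = 0.0085; 1 rose, 1 over the list alone), with adjusted p of 0.853 and 0.864. Quantile-normalized medians were -0.035 for synaptic and -0.033 for chromatin genes with RNAPolII, and -0.153 for detoxification and 0.023 for ribosomal protein genes with H3K4me3. With the covariate none of these 4 lists stayed past the test.

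The dsx comparison asked the same of doublesex, though the labels give dsx flies alone as mutant in white as well. Peaks over white also changed in Or47b and Or67d, as given above. Outside the dsx locus, changes included losses at sand and over a group of genes on 3L and gains at Prp4k, rec and a cluster of prolyl hydroxylase and protease genes. H3K4me3 rose at 497 peaks and fell at 287. edgeR called 435 and DESeq2 454 (360 higher, 94 lower), both also without CS GH 2. The count was 459 without CS GH 1, 325 without CS GH 2, 2518 without CS GH 3, 342 without CS SH 2, 344 without dsx GH 3, 1560 without dsx SH 1 and 293 without dsx SH 3. A replicate block gave 2437. With the covariate there were 264. RNAPolII rose at 201 and fell at 186, with 250 calls without CS GH 2, 1132 in a fit on only the libraries compared (406 higher, 726 lower) and 1190 with the covariate (968 higher, 222 lower). H3K4me3 rose at the splicing kinase gene Prp4k on 3L at 209531 to 209725 from 6.65 ± 3.41 to 228 ± 13.1 (5.04, adjusted p = 9.64e-22). It rose at the meiotic gene rec on 3R at 15832027 to 15832647 from 66.5 ± 8.32 to 295 ± 23.9 (2.14, adjusted p = 1.38e-22). It fell at sand from 588 ± 72.0 to 21.6 ± 7.73 (-4.76, adjusted p = 4.52e-47). At spartin it fell from 90.7 ± 20.1 to 19.5 ± 3.49 (-2.15, adjusted p = 3.21e-22), a direction opposite to Or67d and fru. At Agpat2 it fell from 129 ± 18.2 to 21 ± 3.17 (-2.57, adjusted p = 1.73e-18). The rise of Src64B (1.37) was lost under edgeR, with the covariate, and without CS GH 2, CS SH 2 or dsx SH 2.

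The clock gene per and the insulator gene CTCF fell with both antibodies in dsx. H3K4me3 at per fell from 462 ± 63.7 to 220 ± 28.1 (-1.07, adjusted p = 2.62e-14) and RNAPolII from 658 ± 96.7 to 364 ± 40.0 (-0.85, adjusted p = 0.000323). CTCF fell from 1334 ± 142 to 938 ± 60.4 with H3K4me3 (-0.50, adjusted p = 8.03e-06) and from 1380 ± 82.1 to 922 ± 39.9 with RNAPolII (-0.58, adjusted p = 3.38e-07). H3K4me3 at tailless (tll) fell from 37.2 ± 7.58 to 18.6 ± 5.33 (-0.99, adjusted p = 0.00586) and at Ir84a, an ionotropic receptor gene with a part in courtship (-0.99, adjusted p = 0.0324). RNAPolII rose over PH4alphaEFB and Jon99Fii on 3R at 30482870 to 30488040 (428 ± 14.1 against 214 ± 17.3, 1.00, adjusted p = 5.41e-11) and over the adjoining Jon99Fi, PH4alphaSG2 and PH4alphaMP at 30488505 to 30493998 (422 ± 13.2 against 181 ± 8.37, 1.21, adjusted p = 1.64e-12). It was nearly lost over GluClalpha and Acsx1L on 3R at 19772889 to 19774478 (0.373 ± 0.579 against 54.4 ± 20.3, -5.34, adjusted p = 4.98e-18). At kirre on X at 2799138 to 2799892 it was 0 in all 6 dsx libraries against 23.7 ± 3.52, at least 7.2-fold lower. Tdg on chromosome 4 at 545668 to 548457 fell from 339 ± 26.1 to 158 ± 16.6 (-1.10).

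Of the 7 lists that passed in dsx with H3K4me3, 6 had passed in Or67d in the same direction. Both mutants were compared with the same CS libraries, which alone can make lists alike. Both also had a larger spread between strong and weak peaks than CS, which can do so too. Against a median of 0.095 over all genes, detoxification genes were lower (-0.45, adjusted p = 9.63e-05; 1 rose and 1 fell, 5 called adjusted over the list alone; 0.0634 with an estimated correlation). So were immune genes (-0.368, adjusted p = 0.0188; 1 fell, 3 over the list alone; 0.0634) and olfactory genes (-0.186, adjusted p = 0.0271; 1 fell, 1 over the list alone; 0.41). Eye genes were lower, too (-0.072, adjusted p = 0.0432; 1 fell, 1 over the list alone; 0.1). Genes linked to social experience or aggression tested as lower (adjusted p = 0.0307; 2 fell, dsx and tll, 2 over the list alone; 0.0634) with a mean of -0.357. Their median was 0.019, so that the mean and the test differ from it in sign, and it was -0.044 after TMM rescaling. The list holds dsx itself, and without it the mean was -0.076 and the call was lost (adjusted p = 0.356). Ribosomal protein genes were higher (0.184, adjusted p = 9.63e-05; 6 rose, 16 over the list alone; 0.755) and so were synaptic genes (0.173, adjusted p = 0.0432; 4 rose, 11 over the list alone; 0.755). Quantile normalization gave medians of -0.259 for detoxification, -0.243 for immune, -0.02 for olfactory, -0.124 for eye and -0.034 for social genes, and 0.017 for ribosomal protein and 0.022 for synaptic genes. Single members that rose were Hsp83 (0.40, adjusted p = 0.00104) and CaMKII (0.36), and spz, a Toll ligand gene, fell (-0.78, adjusted p = 0.000921).

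With RNAPolII 7 lists passed in dsx. Lower were chromatin genes (-0.126, adjusted p = 0.00179; 2 fell, 3 over the list alone) and ribosomal protein genes (-0.087, adjusted p = 0.00322; 1 fell, RpS21, 2 over the list alone). So were synaptic (-0.154, adjusted p = 0.00892; limma called 0), learning (-0.133, adjusted p = 0.0152; 1 fell, Fmr1, 1 over the list alone) and ion channel genes (-0.139, adjusted p = 0.0283; 1 rose, Irk3, 2 over the list alone). Higher were olfactory (0.079, adjusted p = 0.0152; limma called 0) and detoxification genes (0.085, adjusted p = 0.043; limma called 0, 1 over the list alone). Their adjusted p with an estimated correlation were 0.496 for chromatin, ribosomal protein and detoxification, 0.555 for olfactory and 0.602 for the other 3. The medians after quantile normalization were -0.042 for chromatin, -0.038 for ribosomal protein, -0.065 for synaptic, -0.078 for learning and -0.092 for ion channel genes, and 0.096 for olfactory and 0.099 for detoxification genes. With the covariate none of the 7 lists stayed past the test with H3K4me3 or with RNAPolII.

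Neighbouring genes fell together over 3 stretches of RNAPolII. In fru flies 9 of 10 peaks on 3R from 18484274 to 18582441 (98.2 kb) passed, from the changed part of fru across CG7691, CG43210, hemo, CG7694 and fray, with a median log2 change of -0.86 and a range from -1.05 to -0.39. Over this stretch RNAPolII was 52.4% ± 3.72 (SD, n = 6) of CS and H3K4me3 59.3% ± 9.03, and 3 peaks over no gene had a median of -0.80. The neighbouring peaks were at -0.18 and -0.27. In dsx flies 22 of 23 peaks on 3L from 13708474 to 13847854 (139 kb) passed, over bru3, CG8757, CG8750, Tsp68C and the hemocyte gene Hml, with a median of -1.03. There RNAPolII was 50.6% ± 2.89 of CS and H3K4me3 48.8% ± 4.48, and peaks over no gene had a median of -1.04. The neighbouring peaks were at 0.78 and -0.28. The third stretch was the dsx locus, 3R from 7924654 to 7964916 (40.3 kb), where all 13 peaks passed. RNAPolII was 5.13% ± 0.881 of CS and H3K4me3 0.224% ± 0.264, between neighbouring peaks at 0.19 and -0.14. Most of this RNAPolII lay in the first peak, 7924654 to 7927291, with 55.8 ± 11.5 against 79.3 ± 7.3 in CS (-0.52, adjusted p = 0.0277). At the other peaks of the stretch it was nearly absent.

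**Figure D3:**
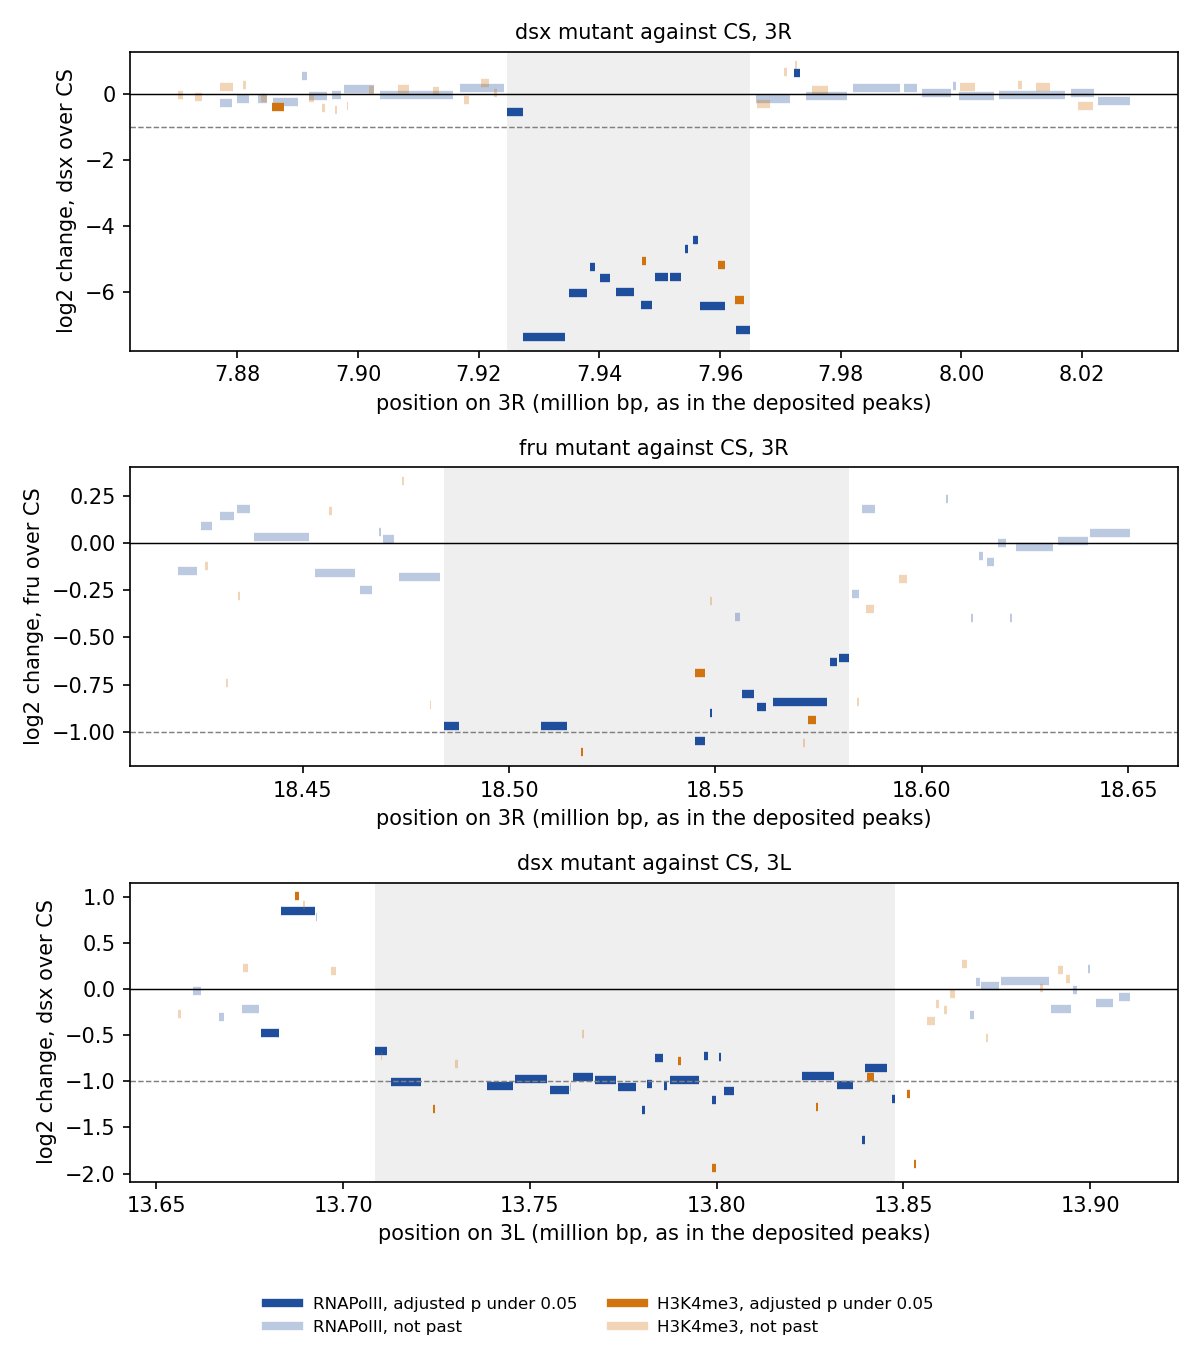
Log2 change of mutant over CS (y axis) at each peak along 3 stretches (x axis, position in Mb), with RNAPolII in blue and H3K4me3 in orange, peaks past the test dark, others pale, the stretch shaded and a dashed line at -1. The median was -1.03 over the dsx stretch of 3L and -0.86 over the fru stretch of 3R. RNAPolII summed over the stretch at the dsx locus fell to 5.13% of CS, most of it in the first peak.

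Some genes changed in all 4 mutants, which share the CS controls. With H3K4me3 14 peaks rose and 6 fell in all 4, of 4691 called in any. CG3397 rose by 1.74 in Or47b, 3.64 in Or67d, 3.52 in fru and 3.33 in dsx, d4 by 2.12, 1.00, 1.08 and 1.44, and the peak over MTF-1 and CG42526 by 0.49, 0.41, 1.73 and 0.84. Agpat2 fell by 2.44, 0.73, 2.47 and 2.57, CPT2 by 0.84, 0.97, 0.87 and 0.88, and the peak over cbc and cid by 0.69, 0.50, 0.74 and 0.69. With RNAPolII Ir41a, Myo81F and a peak over no gene on 2R at 5023772 rose in all 4 and Tdg fell, of 695 called in any. mthl8, in contrast, was lost in Or67d and rose with H3K4me3 in fru (592 ± 79.6 against 202 ± 78.2, 1.62) and dsx (617 ± 63.6, 1.69). In all, 40 H3K4me3 and 20 RNAPolII peaks went in opposite directions in 2 mutants.

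Pairs of mutants shared calls, while 20 simulations of unchanged groups with common controls gave a mean of 0. Unchanged groups yield almost no calls to share, so that count decides nothing. Counts under independence were computed from calls made with all CS libraries, so they do not compare with the counts from different CS libraries. fru and dsx shared 94 higher and 39 lower H3K4me3 peaks, against 6.27 and 2.71 under independence and 32 and 24 with different CS libraries for each. Their log2 changes correlated at r = 0.641 across peaks, against 0.502 simulated and 0.382 with different CS libraries, with a covariance of 0.074 against 0.0267. Or67d and dsx shared 367 and 177 (87 and 35.8 under independence, 46 and 16 with different CS libraries; r = 0.641 against 0.498 and 0.375; covariance 0.104 against 0.0265). With RNAPolII fru and dsx shared 68 and 34 (1.13 and 0.9, 37 and 11; r = 0.552 against 0.499 and 0.31; covariance 0.0389 against 0.0143) and Or47b and Or67d 29 and 25 (0.325 and 0.307, 21 and 18; r = 0.508 against 0.502 and 0.209; covariance 0.0287 against 0.0145). The other 4 RNAPolII pairs, a receptor mutant with fru or dsx, shared 15 to 25 higher and 7 to 25 lower peaks (0.358 to 1.02 and 0.261 to 1.06 under independence, 6 to 11 and 4 to 11 with different CS libraries). Their r, 0.333 to 0.38, lay below the simulated 0.499 to 0.5 (0.07 to 0.126 with different CS libraries), with covariances of 0.0193 to 0.0249 against 0.0144. The other 4 H3K4me3 pairs shared 28 to 116 and 18 to 55 (0.782 to 32 and 0.519 to 17.1; 5 to 35 and 9 to 16), with r from 0.558 to 0.579 against 0.499 to 0.503 (0.206 to 0.395 with different CS libraries) and covariances of 0.0506 to 0.0805 against 0.0266 to 0.0269. Or67d and dsx both had a larger H3K4me3 spread between strong and weak peaks than CS (5.84 and 5.62 against 5.24). This can move strong peaks up and weak peaks down in both, and different CS libraries do not remove it. Sharing with the covariate was not tested. Peaks are not independent of each other, so these correlations carry no p.

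Social isolation was the treatment common to all genotypes, and the housing comparisons asked whether being alone alters brain chromatin. In CS limma called 0 peaks with either antibody, as did edgeR and DESeq2, with 373 of 14513 H3K4me3 and 732 of 21076 RNAPolII peaks at an unadjusted p under 0.05. With RNAPolII quantile normalization gave 1 call and a fit on only the libraries compared 4. The 95% interval of the change lay within 2-fold for 68.4% of H3K4me3 and 87.6% of RNAPolII peaks. In data simulated on this comparison limma called 34.3% and 19.4% of peaks changed by 1.5-fold. The smallest unadjusted p values included H3K4me3 at the actin-bundling gene singed (sn) on X at 7978968 to 7979813, 26.9 ± 6.07 alone against 9.81 ± 3.98 in groups (1.40). They also included H3K4me3 over dpr11 and Pif2 on 3R at 6549094 to 6549793, 13 ± 4.52 against 31.5 ± 6.15 (-1.26), both with adjusted p = 1. With RNAPolII they included su(r) on X at 9197025 to 9200500 (174 ± 15.4 against 117 ± 5.81, 0.56) and Pzl on 3R at 2938393 to 2941132 (57.2 ± 5.17 against 83.5 ± 4.68, -0.54), again with adjusted p = 1.

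In the main limma fit, housing calls appeared in Or47b flies only, with H3K4me3, where 1 peak rose and 4 fell. As many as 3823 peaks (26.3%) had an unadjusted p under 0.05. The strong 25% of peaks was higher (median 0.27) and the weak 50% lower (-0.32) in isolated flies. UQCR-11, a respiratory chain gene, rose on 3L at 25120644 to 25122149 (918 ± 155 against 567 ± 53, 0.69, adjusted p = 0.0365). Map205 fell on 3R at 32057739 to 32058510 (7.39 ± 5.9 against 25.6 ± 3.43, -1.89, adjusted p = 0.0389), and so did the peak over Loxl1 and CG11334 at 31458214 to 31461129 (50.4 ± 8.62 against 112 ± 8.68, -1.15, adjusted p = 0.0164). CG8468 fell on 2R at 14227373 to 14229891 (72.9 ± 2.89 against 151 ± 21.3, -1.03, adjusted p = 0.0365) and CG13062 on 3L at 16314345 to 16314918 (6.29 ± 2.28 against 27.8 ± 8.04, -1.99, adjusted p = 0.0456). In each, 3 of 3 isolated libraries lay on one side. The balance of higher and lower calls differed between fits. edgeR called 0 and DESeq2 626 higher and 2 lower, but both also left out Or47b SH 2. A fit with a replicate block called 1829 higher and 684 lower, and a fit on only the libraries compared 265 higher and 356 lower. There were 0 calls without Or47b GH 1, GH 2 or SH 3, 8 without GH 3, 379 without SH 1 (151 higher, 228 lower) and 2 without SH 2. With RNAPolII limma, edgeR and DESeq2 called 0 in Or47b, with 689 at an unadjusted p under 0.05; jeb (-0.68) was among the smallest p (adjusted p = 1).

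For Or47b housing 11 lists passed with H3K4me3, against a median of 0.198 over all genes, with no member called over all genes by limma. Higher in isolated flies were ribosomal protein genes (median 0.269, adjusted p = 1.88e-05, 2 members called adjusted over the list alone) and chromatin genes (0.282, 0.00058, 26 members). So were learning (0.314, 0.00558, 14 members), synaptic (0.292, 0.0197, 15 members) and axon guidance genes (0.262, 0.0385, 10 members), with adjusted p = 0.651 for all 5 with an estimated correlation. Lower were detoxification (-0.317, adjusted p = 0.00058, 1 member), muscle (-0.483, 0.00415, 2 members), neuropeptide (-0.054, 0.0283, 1 member), immune (-0.388, 0.0283, 3 members) and fat body genes (-0.42, 0.0371, 4 members), with adjusted p = 0.0897 for these 5 with an estimated correlation. Olfactory genes were lower too (-0.261, adjusted p = 0.00105, 3 members; 0.172 with an estimated correlation). With the mean of all peaks of a gene, axon guidance genes were instead lower (adjusted p = 0.0017), and synaptic and learning genes turned lower without passing (adjusted p = 0.436 and 0.447). With the replicate block axon guidance genes did not pass (adjusted p = 0.0694). With the covariate 0 of the 11 lists stayed past the test. After quantile normalization the medians were 0.006 for ribosomal protein, 0.024 for chromatin, 0.032 for synaptic, 0.083 for learning and 0.049 for axon guidance genes. They were then -0.101 for detoxification, -0.203 for muscle, -0.022 for neuropeptide, -0.157 for immune, -0.185 for fat body and -0.065 for olfactory genes. The spread between strong and weak peaks was 5.74 ± 0.273 in isolated and 5.18 ± 0.201 in grouped Or47b libraries (exact permutation p = 0.1, the smallest that 3 against 3 allow). It rose with the replicate number in both housings, with 5.47, 5.72 and 6.02 in isolated and 4.99, 5.15 and 5.39 in grouped libraries. The permutation test does not take such pairing into account.

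In Or67d, fru and dsx limma, edgeR and DESeq2 called 0 housing peaks with either antibody. Unadjusted p were under 0.05 for 564, 529 and 342 H3K4me3 and 642, 747 and 886 RNAPolII peaks. Without Or67d GH 1 there were 2 and without Or67d GH 2 1 H3K4me3 calls in Or67d, and without dsx GH 1 or dsx GH 2 there was 1 RNAPolII call in dsx. Quantile normalization gave 1 and the covariate 2 H3K4me3 calls in Or67d. Among values not past the test, H3K4me3 at Sur on 2L at 10184643 to 10185207 was 4.82 ± 1.8 in isolated against 17.8 ± 2.02 in grouped Or67d flies (-1.74, adjusted p = 0.225). At the channel gene Trpgamma on 2L at 16672115 to 16672798 it was 30.5 ± 5.46 against 11.3 ± 3.98 (1.40, adjusted p = 0.345). In fru flies RNAPolII at mol on 2L at 14980655 to 14984321 was 94.3 ± 7.71 against 140 ± 9.68 (-0.57, adjusted p = 0.878). In dsx flies RNAPolII at CG12541 was 6.57 ± 0.298 against 22.8 ± 4.9 (-1.63), at the sodium channel gene para -1.41 and at the neuronal identity gene acj6 -1.10, all with adjusted p = 0.95.

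For fru housing 6 lists passed with H3K4me3, with 0 members called by limma over all genes or adjusted over the list alone and a median of -0.084 over all genes. Eye and photoreceptor genes were higher in isolated flies (0.07, adjusted p = 0.00152, and 0.0216 with an estimated correlation), as were learning (0.066, 0.00127, and 0.617), neuropeptide receptor (0.055, 0.00586, and 0.371) and juvenile hormone or ecdysone genes (0.044, 0.0193, and 0.292). Ribosomal protein (-0.133, 0.000361, and 0.746) and chromatin genes (-0.129, 0.0278, and 0.746) were lower. For dsx housing 3 lists passed with 0 members called either way: ribosomal protein genes were higher (0.118, adjusted p = 8.22e-05, and 0.702 with an estimated correlation), detoxification (-0.192, 0.00623, and 0.173) and muscle genes (-0.204, 0.0202, and 0.173) lower. After quantile normalization the fru medians were -0.011 for ribosomal protein, -0.002 for chromatin, 0.08 for eye, 0.109 for learning, 0.029 for neuropeptide receptor and 0.114 for hormone genes. Those of dsx were 0.02 for ribosomal protein, -0.091 for detoxification and -0.106 for muscle genes. With the covariate 4 of the 6 fru lists and 0 of the 3 dsx lists stayed past the test. No list passed for housing with RNAPolII.

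Differences of housing effects asked whether a mutant responds otherwise to isolation than CS. limma called 0 peaks in all 8 such comparisons. For Or47b, Or67d, fru and dsx 1651, 431, 290 and 359 H3K4me3 and 798, 581, 686 and 813 RNAPolII peaks had an unadjusted p under 0.05. edgeR and DESeq2 called 0 in 7 of them and 50 and 686 for Or47b with H3K4me3, where both also left out CS GH 2 and Or47b SH 2. Leaving out CS GH 2 gave 117 and leaving out Or47b SH 1 gave 1 H3K4me3 call for Or47b, and leaving out CS SH 2 or Or67d GH 2 gave 1 for Or67d. The 5 housing calls of Or47b are thus not shown to be particular to that mutant: UQCR-11 differed by 0.93 (adjusted p = 0.189) and CG8468 by -1.27 (adjusted p = 0.411). Other values not past the test were ec at 3.37 in Or67d (adjusted p = 0.934), dpr11 and Pif2 at 1.89 in fru (adjusted p = 1) and the RNA-binding protein gene Rbp6 at -2.32 in dsx (adjusted p = 0.999) with H3K4me3. With RNAPolII they were the phosphatase gene phu at -0.80 in Or47b, Cht6 at 1.43 in Or67d, ZAP3 at -2.60 in fru and Cph at -1.37 in dsx (all with adjusted p = 1). Gene lists passed in 14 cases with H3K4me3 and 1 with RNAPolII, which became 1 and 0 with an estimated correlation.

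Over all tested peaks, housing effects in CS and in each mutant were not correlated beyond the error. With H3K4me3 r was 0.05 for Or47b (jackknife SE 0.371), 0.001 for Or67d (0.025), 0.057 for fru (0.065) and -0.003 for dsx (0.127), and with RNAPolII -0.016 (0.057), 0.029 (0.036), 0.026 (0.048) and 0.018 (0.093). Across the 7715 genes with both antibodies, changes of the mark and the polymerase were not correlated beyond about 2 SE either: r was -0.071 for Or47b against CS (jackknife SE 0.187), -0.009 for Or67d (0.201), 0.015 for fru (0.18) and -0.188 for dsx (0.114), where genes are not independent replicates. At the genes called with both antibodies directions mostly matched, for 11 of 14 genes in Or67d, 16 of 17 in fru and 28 of 32 in dsx, per among the latter. In Or47b 0 genes were called with both by limma on the strongest peak of each gene.

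The remaining 9 lists passed in none of the 26 comparisons. Their smallest adjusted p were 0.0514 for activity-regulated genes, 0.0525 for glia markers, 0.0692 for acetylcholine, GABA and glutamate genes, 0.0837 for hemocyte markers, 0.0848 for heat shock genes, 0.116 for neuron markers, 0.145 for sex determination genes, 0.16 for clock genes and 0.197 for dopamine, serotonin and octopamine genes. Single members of these lists did change in the mutants, as given above for per, Hsp83 and Hml.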

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

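All tests of explanations and the counts of other splits in this part were chosen after the results were seen, as was the covariate for the spread between strong and weak peaks.

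Gene lists whose H3K4me3 housing effect differed from that in CS, by a test of the difference itself, were picked out for Or47b, fru and dsx. In Or47b, against a median difference of 0.18 over all genes, ribosomal protein genes (median 0.274, adjusted p = 2.3e-05), chromatin genes (0.28, adjusted p = 0.0062), learning genes (0.301, adjusted p = 0.00799) and synaptic genes (0.285, adjusted p = 0.02) were higher. Lower were olfactory genes (-0.36, adjusted p = 0.00799), detoxification genes (-0.251, adjusted p = 0.00799), muscle genes (-0.458, adjusted p = 0.0119), neuropeptide genes (-0.075, adjusted p = 0.0119), immune genes (-0.25, adjusted p = 0.0255) and fat body genes (-0.393, adjusted p = 0.0468). After quantile normalization the medians were -0.002 for ribosomal protein, 0.043 for chromatin, 0.076 for learning, 0.04 for synaptic and 0.059 for detoxification genes. They were then -0.085 for olfactory, -0.256 for muscle, -0.095 for neuropeptide, -0.124 for immune and -0.149 for fat body genes. With an estimated correlation these adjusted p were 0.677 for ribosomal, chromatin and synaptic, 0.636 for learning, 0.325 for olfactory, 0.222 for detoxification and 0.136 for the other 4. With the mean of all peaks of a gene, synaptic and learning genes turned lower without passing (adjusted p = 0.513 and 0.104), and 7 of the 10 lists stayed. On peaks over 1 gene only 2 stayed. With the replicate block fat body genes did not pass (adjusted p = 0.0642). Over all genes limma called 0 members of these lists, and adjusted over the list alone 2 synaptic, 1 neuropeptide and 1 fat body gene.

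In fru the eye and photoreceptor genes differed (median 0.131 against -0.081 over all genes, adjusted p = 0.00495, and 0.0287 with an estimated correlation). That call was lost with the mean of the gene's peaks (adjusted p = 0.0505) and on peaks over 1 gene only (adjusted p = 0.0728). Also different were learning genes (0.073, adjusted p = 0.00495, and 0.823) and ribosomal protein genes (-0.124, adjusted p = 0.0262, and 0.823). In dsx ribosomal protein genes differed (0.147, adjusted p = 0.000631, and 0.814), and with RNAPolII chromatin genes (-0.121, adjusted p = 0.0178, and 0.897). Quantile-normalized medians were 0.162, 0.111 and -0.013 for the 3 lists of fru, and 0.02 and -0.025 for those of dsx.

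One library lay far from the other 5 of its group in 2 of 22 groups of 6, where chance gives about 1 in 20. Both were levels over the fru stretch of 3R. With H3K4me3 fru SH 3 was at 76.5% of CS against a median of 57.2%, a gap of 0.65 of the whole range. With RNAPolII fru SH 2 was at 59.6% against 51.5%, a gap of 0.706.

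The first pattern is the H3K4me3 difference of strong and weak peaks in Or67d against CS and in isolated against grouped Or47b flies. Or67d and CS libraries held 3758903 ± 845811 and 3798004 ± 934749 reads in peaks (exact permutation p = 0.946, n = 6 each), so a difference in reads in peaks was not seen. The CS value includes CS GH 2, whose reads were recovered with a less sure step. Reads in peaks depend on both sequencing depth and enrichment, so this test cannot decide whether sequencing depth caused the pattern in Or67d. A covariate for the spread of each library kept 115 of 4350 Or67d calls, lowered their median size from 0.429 to 0.0893 while the median SE went from 0.107 to 0.11, and kept 0 of the 10 Or47b lists, which is consistent with libraries that differ in enrichment. A real broad change of the mark in these flies would move the covariate too and stays open. RNAPolII at genes that rose minus at genes that fell differed by -0.058, which decides nothing because RNAPolII peaks are broad.

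The second pattern is the lower signal over the fru stretch of 3R and the dsx stretch of 3L. RNAPolII peaks over no gene, 3 in each stretch, fell about as far (-0.8 in fru and -1.04 in dsx). Because these peaks are few and broad and lie beside the genes, they cannot decide against lower activity of the genes. With RNAPolII at 52.4% and 50.6% of CS and H3K4me3 at 59.3% and 48.8%, a candidate explanation is that 1 of 2 DNA copies is missing there, which for fru would be the fru4-40 chromosome. Reads of total DNA, which would settle it, were not used here.

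The third pattern is the density of RNAPolII calls on the chromosome of the mutated receptor gene, with a ratio of called shares of 7.34 for Or47b and 4.69 for Or67d. It was 1.73 for dsx (Fisher's exact test, adjusted p = 2.28e-06) and 1.06 for fru (adjusted p = 0.763), so the pattern is weaker or absent in the other mutants. Neighbouring peaks can move together, so these p values may be too small. Of the 175 dsx calls on chromosome 3, 13 lay at the dsx locus and 22 in the stretch of 3L. With H3K4me3 the ratio was 4.46 for Or47b but 0.991 for Or67d, with shares of 29.5% and 29.8%. Of those 4350 Or67d calls 115 stayed with the covariate. A change of expression spread evenly over the genome from loss of the receptor would give called shares alike on all large chromosomes. The RNAPolII shares argue against such an even change as the whole cause of the RNAPolII calls. Whether a receptor effect would be even was not tested. Sequence of the parent strain kept around each receptor gene may explain it, and effects of the receptor on genes elsewhere stay open for the calls on other chromosomes.

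Other splits of the same libraries were counted for each comparison. Of 10 splits per housing comparison, too few for a share under 0.05, 10 gave as many calls as the real 0 in CS, Or67d, fru and dsx with H3K4me3 (highest other 2, 2, 1 and 1). In Or47b 1, the real one, gave the 5 calls (highest other 0). With RNAPolII all 10 did so in each genotype (real 0, highest other 0 in CS, 808 in Or47b, 0 in Or67d, 0 in fru and 2 in dsx). The 808 calls came from setting Or47b GH 1, GH 3 and SH 3 against the rest, which points to a structure of those libraries other than housing.

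For the 8 comparisons with CS, 100 of 200 possible splits were drawn, and shares were not adjusted over the comparisons. With RNAPolII, and with H3K4me3 in Or67d, no other split drawn gave as many calls. That is 1 of 100, the smallest share that 100 splits allow, which argues against chance without excluding it. With H3K4me3 in Or47b, fru and dsx the shares lay under 0.05, but some other splits gave more calls than the real one, so chance is not excluded. With H3K4me3 3 of 100 splits gave as many as the 117 calls of Or47b (highest other 1938), 1 as the 4350 of Or67d (1873), 4 as the 320 of fru (1879) and 3 as the 784 of dsx (1773). In Or47b and fru, splits with several times the real count point to a structure of the samples besides genotype. The split with 1773 calls in dsx exchanged only CS GH 3 and dsx GH 2, so its calls still carry much of the genotype difference. With RNAPolII 1 of 100, the real one, gave as many in each mutant (118 in Or47b with a highest other of 30, 227 and 66 in Or67d, 220 and 26 in fru, 387 and 112 in dsx). For differences of housing effects the real count was 0, so 100 of 100 splits gave as many. The highest other was 2669, 4, 1583 and 89 for Or47b, Or67d, fru and dsx with H3K4me3, and 1, 1, 0 and 0 with RNAPolII. The split with 2669 calls kept the real housing groups of Or47b and regrouped only CS. Its calls thus carry the housing difference of Or47b and do not point to a structure apart from it. In fru the split with 1583 calls mixed the housings in both genotypes, which points to a structure of the samples.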

How the results depend on the processing

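Chosen after the results were seen were the covariate for the spread between strong and weak peaks, the omission of 3 RNAPolII libraries together, the lists on peaks over 1 gene and the list without dsx; the other alternatives were planned. With a pseudocount of 10, without a filter and after TMM rescaling all 26 counts of peaks stayed within 1.5 times. TMM rescaling turned the majority of Or67d H3K4me3 calls, from 2540 higher and 1810 lower to 1686 and 2209. No named peak past the threshold reversed. One list did: axon guidance genes in Or47b housing with H3K4me3 went from higher (adjusted p = 0.0385) to lower (adjusted p = 0.0017) with the mean of a gene's peaks. Of 68 list calls 7 changed direction with that mean and 19 with the covariate, of which 1 and 0 passed the threshold in the new direction. For the moves below the cause was not tested, unless given.

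After quantile normalization H3K4me3 gave 1 call for housing in Or47b, 1 for housing in Or67d, 119 higher and 86 lower (about 2.1e+02) for Or47b against CS, 1096 for Or67d and 762 for fru, and RNAPolII 1 for housing in CS. A fit on only the libraries compared gave 621 for housing in Or47b and 3 for the difference of housing effects in Or47b with H3K4me3, and 4 for housing in CS, 430 for fru and 1132 for dsx with RNAPolII. The replicate block gave 2513 for housing in Or47b, 262 for Or47b, 702 for fru, 2437 for dsx and 1 for the difference in Or47b, all with H3K4me3. edgeR gave 0, 1576, 435 and 50 and DESeq2 628, 2017, 454 and 686 for housing in Or47b, Or67d, dsx and the difference in Or47b with H3K4me3. Both also left out the libraries with a less sure step. The covariate gave 0 for housing in Or47b, 2 for housing in Or67d, 172 for Or67d and 264 for dsx with H3K4me3, and 612, 746, 921 and 1190 for Or47b, Or67d, fru and dsx with RNAPolII. Without Or47b GH 3, Or47b SH 3 and Or67d GH 3 RNAPolII gave 1 for housing in Or67d, 181 for Or47b and 442 for Or67d.

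Lists past the threshold, 20 for housing, 23 for genotype and 14 for differences with H3K4me3, became 1, 0 and 1 with an estimated correlation. They became 45, 46 and 30 with the mean of a gene's peaks, and 12, 1 and 3 with the covariate. Peaks over 1 gene gave 10 for genotype and 2 for differences. With RNAPolII, 0, 10 and 1 became 0 for genotype and 0 for differences with an estimated correlation, 1 for housing and 0 for differences with the mean of peaks, and 1 for housing with the replicate block. They became 9, 20 and 11 with the covariate, 2, 5 and 0 on peaks over 1 gene, and 15, 30 and 9 without the 3 libraries.

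Correlations of housing effects with CS over the stronger 50% of peaks were 0.041 for Or67d and 0.172 for fru with H3K4me3, and -0.109 for Or47b and 0.147 for Or67d with RNAPolII. Each moved from its value over all peaks by more than the jackknife SE of that value.

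Leaving out 1 library gave from 0 to 379 calls for housing in Or47b, 0 to 2 for housing in Or67d, 84 to 200 for Or47b, 1869 to 6000 for Or67d, 206 to 695 for fru, 293 to 2518 for dsx, 0 to 117 for the difference in Or47b and 0 to 1 for that in Or67d with H3K4me3. With RNAPolII it gave 100 to 120, 178 to 258, 162 to 211 and 250 to 395 for the 4 mutants and 0 to 1 for housing in dsx. The H3K4me3 extremes were without CS GH 3 (200 for Or47b, 6000 for Or67d, 2518 for dsx), CS GH 2 (1869 for Or67d, 117 for the difference in Or47b), CS SH 2 (206 for fru), fru SH 1 (695 for fru), dsx SH 3 (293 for dsx) and Or47b SH 1 (379 for housing), and for RNAPolII of dsx CS GH 2 (250). All other counts stayed at 0. Of 165 named peaks past the threshold 144 stayed past it under all settings run and 21 were lost under at least 1, 13 of them with 1 library left out.

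Small changes were called less often, more so at weak peaks. Libraries of a group differed by more than counting error, with a chi-square per degree of freedom from 1.86 to 13.9 between pairs, and how much of the limit comes from depth was not tested. Of peaks changed by 1.5-fold in the simulated CS housing comparison, 34.3% were called with H3K4me3 and 19.4% with RNAPolII, and of those with a mean value over 50, 62.9% and 38.7%.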

Other observations

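The tests in this part were chosen after the results were seen.

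RNAPolII libraries of Or47b GH 3, Or47b SH 3 and Or67d GH 3 stood apart from the others, and all carry replicate number 3 in the sample titles. Without them 181 RNAPolII peaks were called for Or47b against CS and 442 for Or67d, against 118 and 227 with them.

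The RNAPolII spread between strong and weak peaks was lower than in CS (3.58 ± 0.067) by -0.095 in fru (exact permutation p = 0.0152, n = 6 each) and by -0.127 in dsx (exact permutation p = 0.00649), and not past 0.05 in Or47b (-0.013, p = 0.81) and Or67d (-0.042, p = 0.407).

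Sequences not placed on a named arm held 46 of 118 RNAPolII calls in Or47b, 65 of 227 in Or67d, 52 of 220 in fru and 64 of 387 in dsx, with 281 such peaks tested. Chromosome 4 had H3K4me3 calls at 52.8% of 163 tested peaks in Or67d, 16% in dsx, 10.4% in fru and 2.45% in Or47b. On chromosomes 2, 3 and X the shares were 29.5% to 29.8% in Or67d, 5.04% to 6.05% in dsx, 1.79% to 2.56% in fru and 0.125% to 1.25% in Or47b. This difference was not tested.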
